A study of Mus musculus with 3 samples.

How the data were processed

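Gene expression was measured in kidney RNA from male C57BL/6J mice aged 16 weeks, 1 uninephrectomy-alone sample and 2 cardio-renal syndrome samples, each on 1 single-colour Affymetrix array of 45101 probe sets. Per the labels' protocols, the cardio-renal model combined banding of the abdominal aorta with removal of 1 kidney 2 weeks later, and the remaining kidney was taken 6 weeks after that removal. RNA was extracted by a guanidinium-phenol method and 250 ng of total RNA was turned into biotin-labelled cRNA with a 3' in vitro transcription kit, per the labels' protocols. A 3' kit reads the end of the transcript, so isoforms that share their 3' end are not separated.

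The deposited values are intensities, the MAS5 signal of each probe set on a linear scale; per the submitters' processing notes they were made with MAS5, and its version is not given in the sources used here. The mean of each array's deposited intensities, trimmed by 2% at each end, was 500, which is the target MAS5 scales to, so no further normalization was applied. MAS5 subtracts mismatch probes, which makes dim probe sets noisy, and the values used here carry no detection calls. The number of arrays limits the precision, and no value has a counting error of its own.

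Probe sets were named from the platform's annotation table, with symbols looked up through the Entrez ID in a RefSeq gene table for GRCm38.p6. Of the probe sets, 34958 had 1 gene symbol, 932 had several and were not named, 9160 were unnamed here and 64 were controls. One gene that was to be reported in any case, also a member of the list called JAK-STAT signalling here, had no named probe set and is not reported here. Each of 18194 genes was represented by its probe set with the highest mean over the 3 arrays. Intensities were turned into log2(value + 28.8), the offset being the median over arrays of the 25th percentile, and genes were kept when their mean reached 7.01, the median of all probe sets, which left 11147 genes. All differences are on this log2 scale, which understates the change of dim genes.

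The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) over all 3 arrays, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit has 1 residual degree of freedom, from the pair of cardio-renal arrays, and assumes that the lone uninephrectomy sample varies like them. The labels do not say whether an array holds RNA of 1 mouse, so p-values measure only the spread between these samples. Because there is 1 control, genes at least 2-fold apart from it in both cardio-renal arrays were counted without a test, and the same count was made with each array in turn as the lone one.

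34 gene lists (nephron segments and other cell types, injury, fibrosis, signalling and stress responses) were fixed before the data were examined, as were the tests, the filter and the rule for named genes. Of the distinct list genes, 655 of 716 had a probe set and 526 were kept. The median difference of each of the 27 lists with at least 5 kept genes was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart when its percentile was over 99.5 or under 0.5 for the mean of both arrays and over 97.5 or under 2.5, on the same side, in each. This describes these arrays and treats genes as independent; limma's camera was the alternative. The rule named the 10 genes furthest above and the 10 furthest below the uninephrectomy array, ranked by the smaller of the 2 arrays' differences and leaving out predicted genes, and up to 4 members per list ranked the same way; other genes named in the text were chosen after their values were seen. Lists of heart markers and of glucocorticoid and FOXO targets were added after the data were seen. The heart list holds every heart gene that was looked up. Apart from the 4 that prompted it, its members were chosen by name before their own values were looked up, 9 of them after those of the rest. *Fabp3*, *Ckm*, *Mb*, *Myh7* and *Acta1* were also members of lists fixed in advance, so not all values were certain to be unseen. A first version of the heart list had left out 9 of the members chosen first, mostly flat or lower, after their values were seen. They were restored, and the test of dim signals was settled only after both versions and the 9 chosen last had been examined. The list was measured without the filter because kidney holds little of these transcripts.

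The fit was tested on 20 simulated data sets of the same 11147 genes, with 200 changed genes and noise drawn from the difference between the cardio-renal arrays. At a true log2 change of 2, the adjusted p recovered 61.3% of changed genes and the 2-fold rule 99.2%; at a change of 1 they recovered 3.9% and 33.4%. On average 10.7 unchanged genes passed the adjusted p, and 16.8 unchanged genes were at least 2-fold higher and 16.6 at least 2-fold lower in both simulated arrays. Of 40 simulated lists of 20 genes shifted by 0.3, 39 stood apart, against 0 of 40 unchanged lists. Alternatives were other offsets, filters, normalizations, probe set rules, variance models, size thresholds and list tests, and leaving out each cardio-renal array.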

Results

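Kidney expression profiles were obtained from 1 mouse kidney sample with uninephrectomy alone and from 2 samples of a cardio-renal syndrome model, in which the abdominal aorta was also banded. The comparison asks which kidney transcripts differ when aortic banding is added to the loss of 1 kidney. Median MAS5 signals were 100.1 on the uninephrectomy array, 105.9 on cardio-renal array 1 and 102 on cardio-renal array 2. The 3'/5' signal ratio of the actin control was 1.72, 1.72 and 1.73 on the same arrays, and that of the Gapdh control was 0.744, 0.782 and 0.732. Across 11147 genes, the uninephrectomy array correlated with cardio-renal array 2 at r = 0.9897 and with cardio-renal array 1 at 0.982, and the cardio-renal arrays correlated with each other at 0.9824. These correlations are across genes, which are not independent replicates. At least 2-fold differences separated 46 genes between the uninephrectomy array and array 2, 122 between it and array 1, and 111 between the cardio-renal arrays themselves.

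The genes furthest above the uninephrectomy array in both cardio-renal arrays were led by transcripts of heart muscle. *Myh6*, the alpha cardiac myosin heavy chain, had a signal of 9.93 with uninephrectomy alone and of 349.4 and 188.2 in the cardio-renal arrays, a mean log2 difference of 2.89 ± 0.57 (SD, n = 2); its other, dimmer probe set had signals of 4.93, 17.2 and 5.49. *Actc1*, cardiac alpha actin, lay 2.29 ± 0.30 higher (SD, n = 2), with signals of 72.7, 545 and 400. *Myl2*, the ventricular myosin light chain, lay 1.93 ± 0.25 higher, with signals of 55.9, 336.8 and 257.1. *Igfbp1*, a secreted binding protein of insulin-like growth factors, lay 1.65 ± 0.10 higher, from 179.2 to 658.3 and 592.3. *Zbtb16*, a zinc-finger transcription factor, lay 1.71 ± 0.63 higher. *Slc7a12*, an amino acid transporter, lay 4.64 higher in array 1 and 1.58 higher in array 2. The other named genes were *Golga7b* (2.03 ± 0.05), *Lce1h* (1.67 ± 0.32), *Atxn7l2* (1.38 ± 0.21) and *Nkx2-6* (1.30 ± 0.10), whose uninephrectomy signals of 27.3, 54.8, 72.1 and 43.1 were all below the array's median. In limma's fit none of these 10 genes passed Benjamini-Hochberg adjustment, and the lowest adjusted p, 0.142, belonged to *Actc1* and to *Ccn1*.

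Among the genes furthest below the uninephrectomy array, *Ccn1*, a matricellular immediate early gene, had signals of 2391, 777.9 and 671.9, a mean log2 difference of -1.69 ± 0.14 (SD, n = 2). *Rarres2*, which encodes the adipokine chemerin, stood at -1.28 ± 0.04, with signals of 1909, 756.4 and 783.9. The transcription factor gene *Fos* stood at -1.30 ± 0.38 and the inducible heat shock protein gene *Hspa1a* at -1.08 ± 0.31. *Ang* and *Rnase4*, neighbouring ribonuclease genes that share promoters, stood at -1.40 ± 0.51 and -1.43 ± 0.64. *Akr1c18*, a steroid-metabolising reductase, stood at -4.68 in array 1 and -1.29 in array 2. *Slc51a*, a bile acid and steroid transporter subunit, stood at -1.36 ± 0.65. *Lacc1* and *Tmod1* completed the 10, at -1.08 ± 0.09 and -1.02 ± 0.11. The probe set used for *Ccn1* may cross-hybridise by its design, and its 3 other probe sets also had lower signals in both cardio-renal arrays. *Hspa1a* and *Hspa1b* are near-identical copies whose probe sets are not certain to tell them apart.

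**Figure D1:**
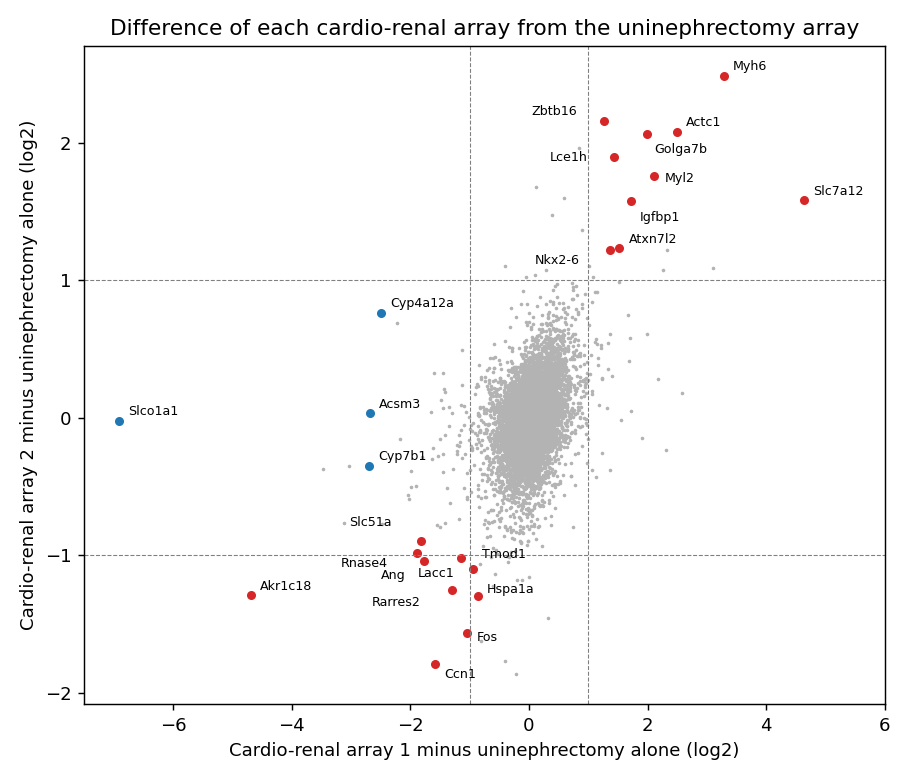
Each point is 1 of 11147 genes, plotted by its log2 difference from the uninephrectomy array in cardio-renal array 1 (horizontal axis) and in cardio-renal array 2 (vertical axis). Dashed lines mark 2-fold differences, red points are the 20 genes named by rule and blue points are 4 male-biased genes. Slco1a1 lies at -6.92 on the horizontal axis and -0.023 on the vertical axis.

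With limma and Benjamini-Hochberg adjustment, 0 of the 11147 genes passed in either direction, and 279 had an unadjusted p under 0.05, where 557 would be expected by chance. Fits without a trend and with a robust trend also gave 0. At least 2-fold differences of the same sign in both cardio-renal arrays were found for 15 genes above and 6 below the uninephrectomy array; without array 1 the genes at least 2-fold higher in both cardio-renal arrays, now array 2 alone, numbered 24 and the genes at least 2-fold lower in both cardio-renal arrays 22, and without array 2 they numbered 53 and 69. With cardio-renal array 1 as the lone array, 20 genes were at least 2-fold higher in it than in both others and 44 lower; with cardio-renal array 2 as the lone array there were 5 and 5. Simulated unchanged genes with the spread of the cardio-renal arrays gave 16.8 higher and 16.6 lower on average, and the counts of 15 and 6 did not exceed these. That spread includes array 1: the SD of log2 differences was 0.318 between the cardio-renal arrays and 0.244 between the uninephrectomy array and array 2. Its noise was drawn from genes of like expression and not from each gene's own spread. The simulation therefore cannot decide whether the counts exceed ordinary scatter. The difference of either cardio-renal array was taken against the same uninephrectomy array, so a shared direction can come from that array alone. Over all genes tested, 3415 were higher in both, 3317 lower in both and 4415 of opposite sign.

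3 of the 27 gene lists compared with random lists stood apart, against 8 without cardio-renal array 1 and 7 without array 2. The heat shock list had 12 of its 18 kept genes lower in both cardio-renal arrays and 0 higher, with medians of -0.29 in array 1 and -0.12 in array 2. *Hspa1a*, *Hspb1* (-0.72 ± 0.06) and *Hspa1b* (-0.74 ± 0.0023) passed limma's test when adjusted over the list alone, while 0 passed over all genes, and the chaperone cofactor *Dnajb1* stood at -0.45 ± 0.09. Camera called the list with the preset correlation (limma adjusted p = 7.39e-08). With an estimated correlation, camera gave an adjusted p of 0.993 for all 27 lists. That estimate rests on 1 residual degree of freedom, so losing a call there says nothing about any single list. The cholesterol biosynthesis list had 11 of 18 genes lower in both arrays and 2 higher, with medians of -0.13 and -0.23 and a camera adjusted p of 0.0142 (limma, preset) against 0.993 (estimated). *Idi1*, the isopentenyl diphosphate isomerase, stood at -0.92 ± 0.75 and the epoxidase *Sqle* at -0.33 ± 0.17, whereas *Srebf2*, the sterol-responsive transcription factor, stood at 0.68 ± 0.15 and the reductase *Dhcr7* at 0.57 ± 0.43. The cholesterol list no longer stood apart after quantile normalization, with a mean of probe sets, or without shared-sequence probe sets. The adipocyte marker list stood apart on the higher side with only 7 kept genes, at medians of 0.31 and 0.33, with 5 genes higher in both arrays and 1 lower; *Car3*, a carbonic anhydrase abundant in fat, lay 1.03 ± 0.17 higher (SD, n = 2) and was its 1 gene past limma's test adjusted over the list alone, against 0 over all genes. The other adipocyte genes named by rule were *Retn* (0.48 ± 0.21), *Thrsp* (0.50 ± 0.26, but -0.06 as the mean of its probe sets) and *Scd1* (0.50 ± 0.37). The abundant adipocyte genes *Fabp4*, at 0.14 and -0.16, and *Lpl*, at -0.59 and -0.0044, were not higher in both arrays, and the list's camera adjusted p was 0.00225 (limma, preset) against 0.993 (estimated). This list no longer stood apart with a mean of probe sets. Among genes in the upper quartile of signals, fewer than 5 of its members remained, too few for the comparison.

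With both cardio-renal arrays, lists for kidney injury, repair and inflammation did not stand apart, except that macrophage markers did without shared-sequence probe sets. Some of them stood apart when 1 cardio-renal array was left out. In array 2 alone, the percentile among random lists was 0 for fibrosis and matrix, 0.02 for macrophage markers and 0.03 for complement and acute phase. In array 1 alone, it was 99.68 for tubular injury and 0.11 for cell cycle genes. The tubular injury list had 9 of 22 kept genes higher in both arrays and 6 lower, with medians of 0.18 in array 1 and 0.014 in array 2. Its members included the immunoglobulin receptor gene *Pigr* at 0.98 ± 0.53, the cell cycle inhibitor *Cdkn1a* at 0.70 ± 0.37, *Cxcl1* at 0.32 ± 0.06 and *Cryab* at -0.31 ± 0.10. The fibrosis and matrix list had 15 of 36 genes lower in both arrays and 1 higher, but its medians lay apart, at 0.056 in array 1 and -0.34 in array 2. *Col6a2*, a collagen VI chain, stood at -0.64 ± 0.31, *Tgfbr2* at -0.35 ± 0.02, fibronectin *Fn1* at -0.32 ± 0.06 and *Postn* at -0.21 ± 0.0039. Macrophage markers had 16 of 27 genes lower and 3 higher, with medians of -0.075 and -0.16; the lysozyme genes *Lyz1* and *Lyz2*, close copies, stood at -0.65 ± 0.11 and -0.60 ± 0.18, *Ms4a7* at -0.46 ± 0.14 and the complement gene *C1qb* at 0.31 ± 0.02. Complement and acute phase genes had medians of 0.017 and -0.30, with the ferroxidase *Cp* at 0.94 ± 0.56 and the neutrophil lipocalin *Lcn2* at -0.34 ± 0.30. Interferon response genes had medians of 0.042 and -0.050, and cell cycle genes of -0.20 and 0.024. Camera with the preset correlation called the fibrosis list (limma adjusted p = 0.00205) and the macrophage list (0.00831). With an estimated correlation, camera's adjusted p was 0.993 for both, as for every list compared.

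Segment markers gave small medians, although the collecting duct list's percentile among random lists was 99.52 in array 1 alone. For proximal tubule markers they were -0.11 and 0.058, with 8 of 29 genes higher in both arrays and 5 lower; the gluconeogenic enzyme gene *Pck1* lay 0.84 ± 0.24 higher, while the organic anion transporter *Slc22a19* stood at -1.91 in array 1 and -0.50 in array 2. Medians were -0.017 and 0.027 for the loop of Henle, 0.046 and 0.017 for the distal convoluted tubule, 0.15 and -0.028 for the collecting duct, 0.020 and -0.11 for podocytes and glomeruli and 0.093 and -0.051 for endothelium. In the collecting duct list, the water channel *Aqp4* lay 0.87 ± 0.48 higher, the sodium channel subunit *Scnn1b* 0.58 ± 0.20 and the ammonia transporter *Rhcg* 0.44 ± 0.07, while the anion exchanger *Slc4a1* stood at -0.48 ± 0.27; 7 of the 18 genes were higher in both arrays and 6 lower. The renin-angiotensin-aldosterone list had medians of 0.10 and 0.030, with *Ace*, the angiotensin-converting enzyme gene, at -0.83 ± 0.64 and the aldosterone-responsive kinase *Sgk1* at 0.49 ± 0.19. The list for JAK-STAT signalling had medians of -0.061 and -0.051, with 7 of 31 genes higher in both arrays and 14 lower; *Il6ra* lay 0.84 ± 0.13 higher, with the opposite sign (-0.3) without shared-sequence probe sets, and *Pim1* 0.59 ± 0.17 higher, and *Epor* stood at -0.56 ± 0.05. *Cyp24a1*, the vitamin D 24-hydroxylase, lay 0.70 ± 0.19 higher in a mineral handling list whose medians were -0.053 and 0.048. None of these genes passed limma's adjusted p.

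**Figure D2:**
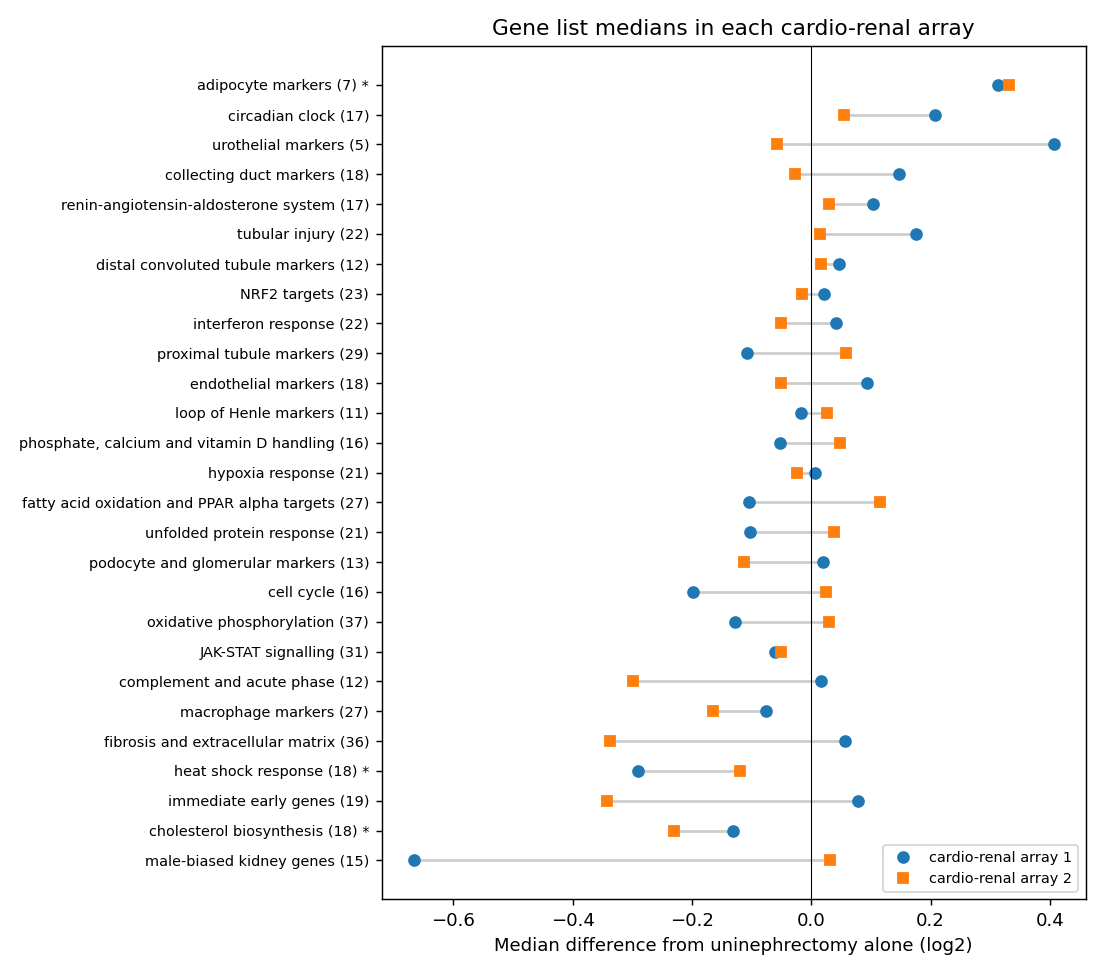
Median log2 difference from the uninephrectomy array (horizontal axis) of each gene list with at least 5 kept genes (number in brackets), for cardio-renal array 1 (circles) and array 2 (squares). Stars mark the 3 lists that stood apart from random lists; the male-biased genes lie at -0.67 in array 1 and 0.032 in array 2.

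Fatty acid oxidation and PPAR alpha targets had medians of -0.10 in array 1 and 0.12 in array 2, where the list's percentile was 99.99. *Pdk4*, the pyruvate dehydrogenase kinase induced in fasting, lay 0.85 and 1.96 higher in arrays 1 and 2. *Angptl4*, a lipoprotein lipase inhibitor, lay 0.59 and 1.59 higher. Oxidative phosphorylation had medians of -0.13 and 0.029, the hypoxia response of 0.007 and -0.024, and NRF2 targets of 0.021 and -0.015. In the unfolded protein response list, with medians of -0.10 and 0.038, the amino acid response genes *Asns* (-0.85 ± 0.11), *Ddit3* (-0.62 ± 0.12) and *Atf4* (-0.54 ± 0.11) stood below the uninephrectomy array and *Sesn2* lay 0.68 ± 0.21 higher. Immediate early genes had medians of 0.078 and -0.34; *Ccn1* and *Fos* passed limma's test adjusted over the list alone and 0 genes passed over all genes, and *Nr4a1* stood at -0.92 ± 0.43 and *Zfp36* at -0.42 ± 0.06. Camera called this list with the preset correlation (limma adjusted p = 0.00306), and the estimated one gave 0.993, as for every list compared. Circadian clock genes had medians of 0.21 and 0.055, with *Bhlhe40* at 0.68 ± 0.15 and *Wee1* at 0.64 ± 0.14; their camera adjusted p was 0.0123 (limma, preset) and 0.993 (estimated). Both of these lists stood apart among genes in the upper quartile of signals, and immediate early genes also without shared-sequence probe sets.

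Sex-biased kidney genes separated the cardio-renal arrays from each other. All 15 kept male-biased genes were lower in array 1 than in the uninephrectomy array, 5 of them at least 2-fold, with a median of -0.67; in array 2, 5 of 15 were lower and the median was 0.032. *Slco1a1*, an androgen-dependent organic anion transporter, had signals of 6161 with uninephrectomy alone, 22.5 in array 1 and 6064 in array 2. *Cyp7b1*, an oxysterol hydroxylase, had signals of 13090, 2003 and 10270, *Acsm3* of 11230, 1721 and 11490, and *Cyp4a12a*, a 20-HETE synthase, of 3238, 550.1 and 5518. The female-biased list held 4 kept genes, too few to place among random lists, with medians of 1.44 in array 1 and 0.21 in array 2. *Slc7a12* had signals of 213.4, 6011 and 695.2, *Abcc4* of 1491, 4986 and 1543 and *Cyp4a14* of 3036, 6832 and 3957, whereas *Slc22a7* had 3985, 459.6 and 3124. Camera called the male-biased list with the preset correlation (limma adjusted p = 0.000699), and the estimated one gave 0.993, as for every list compared. Y-linked *Eif2s3y* had signals of 1213, 1451 and 1483 and *Kdm5d* of 393.3, 490.1 and 421.4, and the sex chromosome list of 3 genes had medians of 0.25 and 0.093; the labels give male mice.

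Markers of tissues near the kidney were checked beside these groups. Few genes of other cell types were kept: 2 for lymphocytes, 3 for erythroid cells, 4 for adrenal gland, 2 for skeletal muscle and 2 for pancreas, with medians in arrays 1 and 2 of 1.38 and -0.45, 0.070 and 0.21, 0.38 and 0.175, 0.18 and 0.037, and -0.065 and 0.003. Among them the noradrenaline-synthesising enzyme gene *Dbh* lay 0.63 ± 0.03 higher and the haemoglobin gene *Hbb-b2* 0.61 ± 0.30 higher. Urothelial markers had medians of 0.41 and -0.057 over 5 genes, with *Upk1b* at 1.04 in array 1 and 0.32 in array 2. A heart marker list was added after *Myh6*, *Actc1*, *Myl2* and *Pln* had been seen. Its other 45 genes were chosen by name before their own values were looked up, 9 of them after those of the rest. *Fabp3*, *Ckm*, *Mb*, *Myh7* and *Acta1* were already in lists fixed in advance. Of the 45, measured without the filter, 30 were higher in both cardio-renal arrays and 6 were lower, with medians of 0.36 in array 1 and 0.25 in array 2 (0.15 in array 2 after quantile normalization). Of the 9 chosen last, 7 were higher in both and 2 lower, with medians of 0.38 and 0.42. Among the members furthest above the uninephrectomy array, chosen after their values were seen, the oxygen-storage protein gene *Mb* had signals of 3.81, 226.4 and 174, cardiac troponin T *Tnnt2* of 12.4, 202.9 and 121.7, cardiac troponin I *Tnni3* of 1.97, 86.3 and 51.6 and the natriuretic peptide gene *Nppb* of 11.1, 115.5 and 142.8. Other heart genes did not share this: troponin C, *Tnnc1*, had signals of 239.8, 241.7 and 238, the fatty acid binding protein gene *Fabp3* of 3597, 3647 and 3580, the calcium pump gene *Atp2a2* of 11260, 8860 and 11120, and the beta myosin heavy chain gene *Myh7* of 66.9, 12.6 and 54.1.

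**Figure D3:**
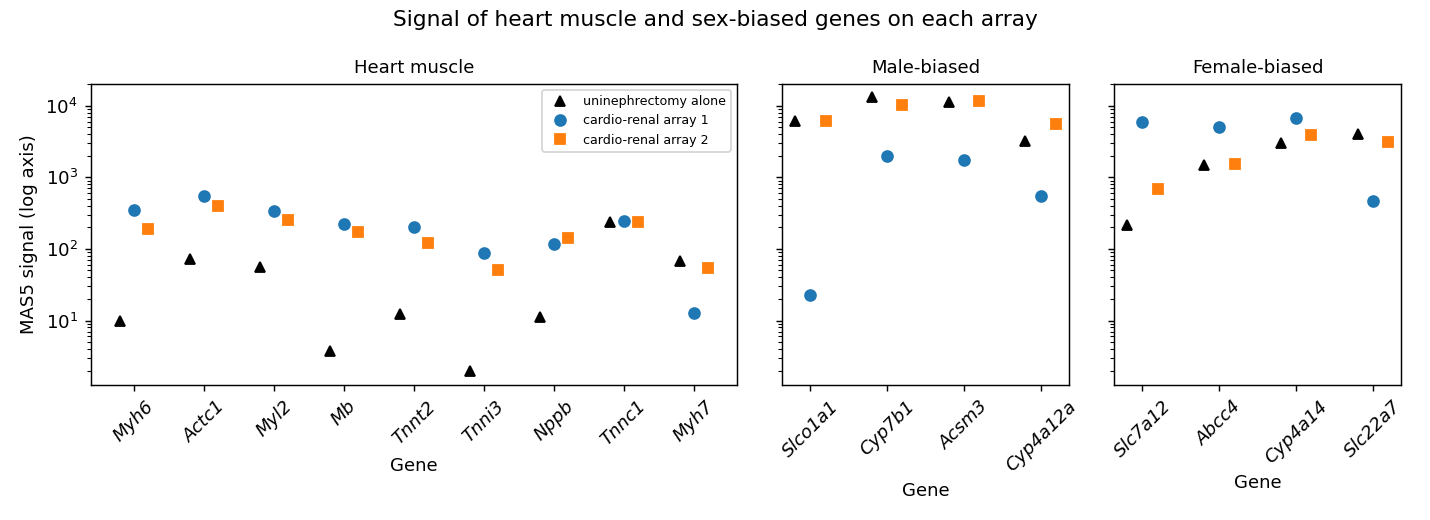
MAS5 signal (vertical axis, log scale) of heart muscle, male-biased and female-biased genes on the uninephrectomy array (triangles), cardio-renal array 1 (circles) and cardio-renal array 2 (squares), 1 point per array. The genes were chosen after their values were seen; 7 of the heart genes are higher on both cardio-renal arrays while Tnnc1 and Myh7 are not, and Slco1a1 has a signal of 22.5 on cardio-renal array 1.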

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

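The tests of explanations in this part were chosen after the patterns had been seen. Outside the named genes, 2445 of the probe sets unnamed here passed the same filter on low values; 11 of them were at least 2-fold higher in both cardio-renal arrays than in the uninephrectomy array, and 3 were at least 2-fold lower. These were set aside because no comparison used them, and they are given as counts only.

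Of 45 heart markers beyond those seen first, 30 were higher in both cardio-renal arrays and 6 lower, and 0 genes passed limma's adjusted p with or without the filter. Of 35 such markers with a uninephrectomy signal under 100, 6 (17.1%, exact 95% interval 6.56 to 33.6%) were at least 2-fold higher in both arrays. Among 7008 other genes as dim, 0.87% were. This argues against scatter of dim probe sets as the whole cause but does not exclude it. The test was settled after the values were seen, treats genes as independent and rests on the list as completed. Of the 8 dim markers chosen after the other values were known, 0 were 2-fold higher (exact 95% interval 0 to 36.9%). RNA from heart tissue in the cardio-renal samples is a candidate explanation that stays open. The median difference was 0.371 over the 45 (bootstrap interval 0.187 to 0.575), above all and 99.91% of 10000 matched random lists in arrays 1 and 2. It was 0.403 over the 9 chosen last (interval -0.103 to 0.77). *Tnnc1*, *Fabp3* and *Atp2a2*, which kidney also expresses, were not higher in both. Nor were some members with a uninephrectomy signal under 100, among them *Myh7* (-1.21 and -0.21 in arrays 1 and 2), *Actn2* (-0.03 and 0.06) and *Myom1* (-0.14 and 0.19). Skeletal muscle markers other than *Ckm*, *Mb* and *Myh7*, which heart also uses, were measured without the filter. These 10 genes, of which *Acta1* is also in the heart list, had a median of 0.122 (bootstrap interval 0.02 to 0.323). This neither excludes nor shows a share from that tissue. Transcription of these genes in the kidney itself, through banding, stays open and untested.

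Male-biased genes were lower in cardio-renal array 1 alone. A female sample is excluded, because the lowest difference of a Y-linked gene there was 0.11; an exchange with another male sample was not tested. A loss shared evenly by proximal tubule cells is excluded as the whole cause. The 27 proximal tubule markers outside the list had a median of -0.039 (bootstrap interval -0.2 to 0.089) against -0.666 for the male-biased genes. A loss confined to part of the proximal tubule was not tested, and 1 of the 27 markers was at least 2-fold lower. Degraded RNA is excluded because the array's 3'/5' control ratios were at most 1.05 times the highest of the other arrays. Lower androgen action in that sample is a hypothesis left open: with the filter lifted, which adds the dim *Abcc3* to the 4 kept female-biased genes, the 5 had a median of 1.163, above all 10000 random lists, but the bootstrap interval ran from -3.039 to 4.64 because *Slc22a7* was lower. Cardio-renal array 2 did not share the pattern over the male-biased list, where 5 of 15 genes were lower and the median was 0.032, so the pattern cannot be assigned to the model. Single genes did move in array 2 as in array 1: *Slc7a12* (1.58), *Cyp4a14* (0.38), *Slc22a7* (-0.35) and *Cyp7b1* (-0.35).

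Of 18 heat shock genes, 12 were lower in both cardio-renal arrays and 0 higher, and 0 passed limma's adjusted p over all genes. Camera called the list with its preset correlation only. With a correlation estimated from 1 residual degree of freedom, it called no list (limma adjusted p = 0.993 for each), which cannot decide about this list. The list's median difference between the cardio-renal arrays was 0.145, against -0.29 and -0.12 from the uninephrectomy array, so the cardio-renal arrays lay no closer to each other than array 2 lay to the uninephrectomy array. A single uninephrectomy sample with a raised stress response cannot be told apart from an effect of the model, because there is 1 such sample.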

How the results depend on the processing

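The count of 0 genes past limma's adjusted p held under every planned setting that can be tested; leaving out a cardio-renal array leaves 1 array against 1 and no test. The 15 genes at least 2-fold higher in both cardio-renal arrays became 74 with no filter, 2 in the upper quartile of signals, 9 with the mean of all probe sets, 57 at 1.5-fold and 4 at 3-fold, and 24 to 53 when 1 cardio-renal array was left out (24 without array 1). The 6 genes at least 2-fold lower in both cardio-renal arrays became 18 with no filter, 3 in the upper quartile, 3 without shared-sequence probe sets, 39 at 1.5-fold and 0 at 3-fold, and 22 to 69 with 1 array left out (22 without array 1). Of the 3 lists that stood apart, 1 did (heat shock) with the mean of all probe sets, 7 to 8 lists did with 1 array left out, and camera called 8 with its preset and 0 with an estimated correlation. Direction turned for *Il6ra* (-0.3) and *Tspan2* (-0.18) without shared-sequence probe sets, for *Ndufb8* there (0.16) and with the mean of probe sets (0.01), for *Emx1* (-0.14), *Ptger3* (0.16), *Slc12a3* (-0.35) and *Thrsp* (-0.06) with that mean. Median centring, which shifts all genes of an array alike, brought *Slc12a3* to 0. The other 1511 gene values kept their direction, and their side of the threshold where a test was run. Of the list medians, 296 moved by less than the spread between the arrays and 42 by more. These counts include the settings with 1 array left out, which say nothing about robustness for genes. There the named genes could not turn, having been named for the same sign in both arrays, and no test was run. The spread used for list medians came from those same 2 arrays. Where no construction (fewer genes, a lower limit, fewer arrays) shows it, the cause was not tested. The alternatives planned for the gene that is not reported here were not run. Removing heart markers from all lists, an alternative added after seeing the data, left 3 standing apart. No paired analysis was possible because the groups share only 1 replicate number, given in accession order. Most named heart genes have dim signals, for which the values used here carry no detection calls.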

Other observations

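Some single genes outside the sex-biased lists differed on cardio-renal array 1 from both other arrays. *Abcb1b*, a multidrug efflux pump, had signals of 67.4, 796.3 and 175.7 on the uninephrectomy array, cardio-renal array 1 and cardio-renal array 2. On cardio-renal array 2 it was also at least 2-fold above the uninephrectomy array. *Dbp*, a clock output gene that cycles strongly with the time of day, had signals of 471.2, 1440 and 464.8, and *Npas2*, of the opposite clock phase, had 324.9, 170 and 301.8. These genes were chosen after their values were seen.

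The genes *Igfbp1*, *Pdk4*, *Fbxo32* and *Zbtb16*, known targets of glucocorticoids or FOXO factors, were among the highest in both cardio-renal arrays. This led to a test added after the pattern was seen. Its prediction was written before the other targets were looked at as a set. Those targets were not all unseen, because *Pck1*, *Sgk1*, *Cdkn1c*, *Bcl6* and *Bnip3* were also members of lists fixed in advance. The test is therefore not independent of the values that prompted it. The 25 other targets had a median difference of 0.219 (bootstrap interval 0.062 to 0.344), with 18 higher in both arrays and 3 lower, and medians of 0.164 in array 1 and 0.226 in array 2, each above all 10000 matched random lists; with median centring the medians were 0.099 and 0.204. *Pck1* had signals of 6364, 12850 and 10150, *Tsc22d3* of 1983, 2751 and 2679 and *Foxo3* of 1017, 1476 and 1515, whereas *Ddit4* had 1324, 795 and 982.2. Higher glucocorticoid or FOXO activity in the cardio-renal mice is therefore a hypothesis that may be followed up; feeding state and time of collection are not given, and with 1 uninephrectomy sample a low value in that sample would look the same.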
